A study of Homo sapiens with 24 samples.

How the data were processed

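Gene expression was measured in 24 samples of SKBR3 cells, 6 each of control, PMCA2 knockdown, NHERF1 knockdown and HER2 knockdown. Per the labels' protocols, cells were infected with shRNA lentiviral particles for 48 h, total RNA was extracted with TRIzol and cleaned on columns, and biotin-labelled cRNA was hybridised to Illumina arrays. The deposited values used here are probe intensities on a linear scale, 1 value per probe and array, which the authors had already normalized. No label or header names the software or the method, and both are not given in the sources used here. From the values, the sorted intensities of the 24 arrays differ by at most 0.372% at any rank, as quantile normalization leaves them, and the smallest is 81.6, so the background had not been subtracted. Their scale is thus known from the values alone. Each array's median is close to 103. A second deposited table of non-normalized signals with detection p-values was not used, because its 24 signal columns carry names that match no label. Groups and replicate numbers come from the labels, and chips and positions from the array titles.

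Probes were named through the platform annotation given for these arrays, matched by gene identifier to the RefSeq gene table of assembly GRCh38.p14, which served for names only. Of 47323 probes, 30113 have 1 gene symbol, 8 have several and 17202 have none listed. Of those with 1 symbol, 30074 matched the gene table. No genome was used and no coordinates are given.

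The design written before the data were examined assumed scanner signals with detection p-values. The usable table has none, so 437 probes of olfactory receptor genes, taken as silent in this line, stood in as negative controls. Background was corrected with normexp against them (offset 16), followed by quantile normalization and log2. A probe counted as above the floor at an intensity over 106, the 95th percentile of those probes, and was kept where this held on at least 6 arrays (22586 probes). Each gene was represented by its probe with the highest mean, giving 12445 genes, 3390 of which had further probes above the floor. Genes of the PSG family or named by the rule below, leaving out the targets, whose probes are described with them, had such a probe of the opposite sign as follows: PRIM1, RFC4, SOD2 and ULK1 for the PMCA2 knockdown with control, BCL2L1, CAMK2D, NFKB2, SAA1, UHRF1 and UNG for the NHERF1 knockdown with control, MCM7, PSG2, SAA1 and UHRF1 for the HER2 knockdown with control, AGR2, GSDMB, INSIG1 and PPP1R1B for the PMCA2 with the HER2 knockdown, AGR2, MCM7, PSG2, PSG6, PSG7, SELENOS, SYVN1, TALDO1, TCEAL9 and UHRF1 for the NHERF1 with the HER2 knockdown, and AGR2, SELENOS and SOD2 for the PMCA2 with the NHERF1 knockdown. No fold given is from a comparison listed there for its gene. Changes of further probes differed by over 1.5 times from that of the probe used for some genes named by that rule or of the PSG family. For the PMCA2 knockdown with control this held for 13 of 49 with such probes: BEX3 (log2 5.94 used, 1.40 to 5.17 for other probes), PSG6 (log2 2.65 used, 0.69 for other probes), SAA1 (log2 2.82 used, 0.33 to 2.17 for other probes) and TCEAL9 (log2 6.95 used, 4.88 for other probes), and, with no change given in that comparison, AGR2, GAS6, LSS, MAGEC2, NCCRP1, PLOD2, PMAIP1, PPP1R1B and TCEAL8. For the NHERF1 knockdown with control this held for 12 of 49: AGR2 (log2 -5.60 used, -2.56 for other probes), BEX3 (log2 6.59 used, 1.96 to 5.92 for other probes), PPP1R1B (log2 -2.41 used, -0.44 for other probes), PSG4 (log2 -2.44 used, -1.03 to -0.92 for other probes) and TCEAL9 (log2 6.83 used, 4.45 for other probes), and, with no change given in that comparison, LSS, NCCRP1, PLOD2, PMAIP1, SAA1, TALDO1 and UNG. For the HER2 knockdown with control this held for 14 of 49: LSS (log2 0.95 used, 0.11 for other probes), PSG4 (log2 -2.91 used, -1.09 to -0.97 for other probes) and TCEAL9 (log2 6.75 used, 4.75 for other probes), and, with no change given in that comparison, AGR2, BEX3, CTH, GAS6, MAGEC2, PCK2, PLOD2, PMAIP1, PPP1R1B, SAA1 and UNG. For the PMCA2 with the HER2 knockdown this held for 16 of 49: CAMK2D (log2 2.14 used, 1.52 for other probes), CTH (log2 -1.99 used, -1.27 to -1.00 for other probes), NCCRP1 (log2 -3.59 used, -1.78 for other probes), PCK2 (log2 -1.08 used, -0.86 to -0.38 for other probes), PMAIP1 (log2 1.37 used, 0.39 for other probes), PSG2 (log2 1.29 used, 0.69 for other probes), PSG3 (log2 2.18 used, 1.47 for other probes), PSG4 (log2 4.54 used, 2.17 to 2.89 for other probes), PSG6 (log2 2.89 used, 0.74 for other probes), SAA1 (log2 3.55 used, 0.44 to 2.15 for other probes) and SOD2 (log2 0.99 used, 0.13 to 1.08 for other probes), and, with no change given in that comparison, GAS6, IGFBP5, MAGEC2, PLOD2 and TCEAL8. For the NHERF1 with the HER2 knockdown this held for 5 of 49: PLOD2 (log2 3.19 used, 0.11 to 0.79 for other probes) and SAA1 (log2 2.12 used, 0.05 to 0.95 for other probes), and, with no change given in that comparison, CAMK2D, GAS6 and NCCRP1. For the PMCA2 with the NHERF1 knockdown this held for 9 of 49: GAS6 (log2 4.04 used, 1.03 to 3.97 for other probes), MAGEC2 (log2 -4.78 used, -3.40 for other probes), PPP1R1B (log2 0.88 used, 0.12 for other probes), PSG4 (log2 4.07 used, 2.13 to 2.83 for other probes), SAA1 (log2 1.43 used, 0.39 to 1.20 for other probes) and TCEAL8 (log2 -4.32 used, -3.71 to -2.98 for other probes), and, with no change given in that comparison, NCCRP1, PSG3 and PSG6.

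Limma 3.58.1 in R 4.3.3 fitted all 4 groups together (lmFit, contrasts, eBayes, 20 residual degrees of freedom) for the 6 comparisons, each knockdown with control and the knockdowns with one another. Adjusted p is Benjamini-Hochberg over the genes tested, with the threshold at 0.05. The 30 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. List members were counted over all genes tested and adjusted over the list alone. Correlations between knockdowns were set against 100 simulations of unchanged groups and repeated with the controls split by chip. The rule for named genes, fixed before the data were examined, took the 3 targets, the 8 largest rises and 8 largest falls in each knockdown among called genes with all arrays on one side of their chip's control mean, the 4 members with the smallest p of each list that passed, the 6 largest shared rises and 6 largest shared falls, and 4 genes per direction between knockdowns, leaving out uncharacterised names. For a list, only members with the sign of its camera direction were taken, so members moving the other way are not named for it. The rule gave 151 tested genes. The comparisons, lists and most alternatives were also set before the data were examined.

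The fit was tested on simulated data for the comparison of the PMCA2 knockdown with control (12445 genes, 50 changed at each size). It recovered 6% of changes of 1.1-fold, 44% of 1.2-fold, 98% of 1.5-fold and 100% of 2-fold, with 6 false among 130 calls. Far fewer genes were changed there than the 8334 called in the real comparison, and the adjusted p depends on that share. These rates thus describe the simulation alone, and recovery at the real share of changes was not tested. Chip effects were tested with chip as a term, and limma called 1 gene between the chips. Alternatives tried were no background correction, median scaling, cyclic loess, another offset, normexp on all probes, no filter and a strict filter at the 99th percentile (115) in place of a planned detection p-value, chip or replicate number as a block, each chip alone, positions averaged across chips, all probes, the mean of a gene's probes, only the groups compared, a trended robust prior, array weights, fold thresholds, other list tests and leaving out each array. Precision is limited by the number of arrays and by the number of cultures, which the labels do not give.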

Results

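SKBR3 is a human breast cancer line that carries many copies of ERBB2, the gene of the receptor tyrosine kinase HER2. Its cells were infected for 48 h with lentiviral particles carrying short hairpin RNAs against PMCA2 (gene ATP2B2, a calcium pump of the plasma membrane), NHERF1 (a scaffold protein with PDZ domains) or HER2, and set beside control cells. The labels give 48 h of infection for the control too, and its source name, SKBR3 control, names no hairpin. RNA of each group was read on 6 Illumina arrays, 24 in all, with 3 arrays of each group on each of 2 chips. The labels name no separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Across genes, arrays of a group on the same chip correlated with a median r of 0.996, arrays of different knockdowns with 0.973, and a control with a knockdown array with 0.918. Each group sits in chip positions of its own, so position on the chip and group cannot be told apart. The median standard error (SE) of a difference between groups was 0.07 in log2. It holds the spread between arrays alone. Precision is limited by the number of arrays and by that of cultures, which is not given. A gene was held as measured on an array where its probe lay above the floor set by olfactory receptor probes. Where it did so on no array of a group, or on so few that the group's mean lay below the lowest signal of measured probes, only a bound is given as at least N-fold. The bound sets the bright group's mean against, per array, the higher of that lowest signal and the dim probe's own.

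The targeted genes were compared first, because they can check the labels and because the series asks how PMCA2 bears on HER2 expression. ERBB2 fell in all 3 knockdowns, to 50.9% of control with PMCA2 knocked down (log2 -0.97, SE 0.04, limma adjusted p = 3.08e-17, n = 6 arrays per group), to 31.5% with NHERF1 (log2 -1.67, SE 0.04) and to 53.3% with HER2 (log2 -0.91, SE 0.04). Its mean log2 intensity was 13.76 ± 0.03 (SD, n = 6) in control and 12.79 ± 0.06, 12.09 ± 0.10 and 12.85 ± 0.03 in the PMCA2, NHERF1 and HER2 knockdowns. ERBB2 was lower in the NHERF1 than in the HER2 knockdown (log2 -0.76, SE 0.04, limma adjusted p = 3.52e-14). It did not pass between the PMCA2 and HER2 knockdowns (log2 -0.07, SE 0.04, limma adjusted p = 0.198). As ERBB2 was no lower in the HER2 knockdown than in the others, its fall does not check the HER2 label. A dimmer ERBB2 probe stood at 67.1%, 54.9% and 67.5% of control in the same order, and another was near the floor in every group. NHERF1 fell to 8.10% of control in its own knockdown (log2 -3.63, limma adjusted p = 1.81e-28), and to 54.1% and 62.9% in the PMCA2 and HER2 knockdowns. ATP2B2 could not be judged. Of its 3 probes, 1 lay above the floor, on 1 NHERF1 knockdown array alone, so the PMCA2 label has no check here. The targets thus cannot tell the PMCA2 and HER2 labels apart. ATP2B2 is given for completeness. Its brightest probe differed from control by -0.04 in the PMCA2 knockdown, untested.

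**Figure D1:**
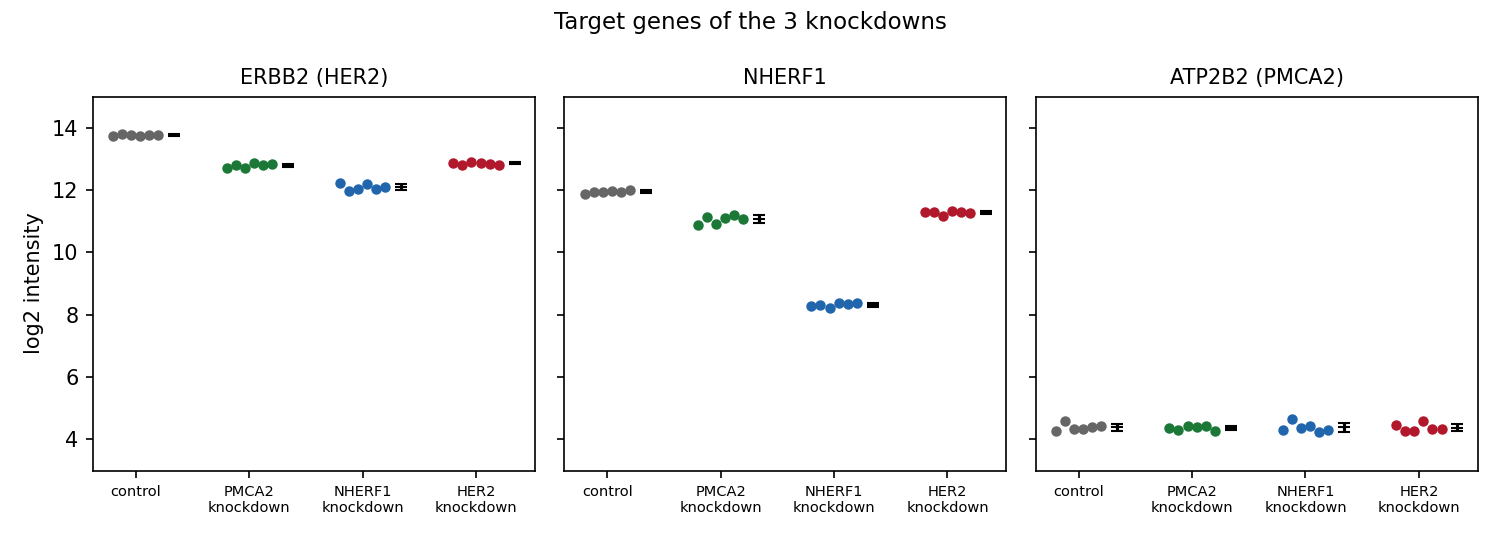
Log2 intensity (vertical axis) of ERBB2, NHERF1 and the brightest ATP2B2 probe by group, 1 point per array, with the mean and SD of 6 arrays as a black mark beside them. ERBB2 is lowest in the NHERF1 knockdown, and ATP2B2 lies at the background level in every group.

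The PMCA2 knockdown was set against control to learn which transcripts differ when the calcium pump is targeted. Genes far above their control level included SLC2A3 148-fold (log2 7.21, SE 0.07, above the floor on 5 of 6 control arrays), HSD3B1 at least 87.1-fold, CAPN6 at least 53.6-fold and IGF2BP3 at least 48.6-fold. SLC2A3 encodes a glucose transporter, HSD3B1 a steroid dehydrogenase and IGF2BP3 an RNA-binding protein of fetal tissue. Also higher were TCEAL9 123-fold (log2 6.95, SE 0.06), PLAC9 73.5-fold (log2 6.20, SE 0.06, above the floor on 4 of 6 control arrays), BEX3 61.5-fold (log2 5.94, SE 0.11) and RCN1 60.4-fold (log2 5.92, SE 0.09, above the floor on 3 of 6 control arrays). SCGB2A2, which encodes mammaglobin, fell at least 73.8-fold, and the transcription factors of luminal cells FOXA1 80.3-fold (log2 -6.33, SE 0.06) and SPDEF at least 45.6-fold. BCAS1 was at least 65.8-fold and MLPH at least 85.7-fold (above the floor on 1 of 6 PMCA2 knockdown arrays) lower. IRX3 was at least 108-fold (above the floor on 2 of 6 PMCA2 knockdown arrays) and IGFBP5 at least 167-fold (above the floor on 1 of 6 PMCA2 knockdown arrays) lower. Also lower were the urea cycle enzyme CPS1 82.1-fold (log2 -6.36, SE 0.08) and the acute phase protein ORM1 at least 55.5-fold. Of the luminal epithelial markers, 3 of 25 rose and 18 fell, and 4 and 19 adjusted over the list alone (median log2 -1.03, camera adjusted p = 8.61e-06). AZGP1 was at least 10.8-fold lower. Mitosis genes moved up together, as 31 of 38 rose and 2 fell, and 31 and 2 adjusted over the list alone (median log2 0.45, camera adjusted p = 2.31e-05). HMMR was 2.47-fold, TPX2 1.91-fold, TOP2A 1.67-fold and CDC20 1.66-fold higher. Among interferon-stimulated genes, 23 of 36 rose and 8 fell, and 23 and 8 adjusted over the list alone (median log2 0.39, camera adjusted p = 0.0141, adjusted p = 0.0549 with an estimated correlation). Of those that rose, the smallest p belonged to IFITM3, IFITM2, IFITM1 and HERC5. IFITM3 was 10.9-fold, IFITM2 6.85-fold, IFITM1 29.3-fold (above the floor on 5 of 6 control arrays) and HERC5 at least 9.28-fold (above the floor on 1 of 6 control arrays) higher. The IFITM probes may read one another's transcripts. For NF-kB and inflammatory cytokines, 15 of 23 rose and 3 fell, and 15 and 3 adjusted over the list alone (median log2 0.51, camera adjusted p = 0.0236). CCL5 was 31.3-fold, SAA1 7.06-fold, TNFAIP8 3.59-fold and IL6 at least 4.37-fold (above the floor on 1 of 6 control arrays) higher. On chip 2 alone this list did not pass (camera adjusted p = 0.0577). Genes of oxidative phosphorylation, the respiratory chain of mitochondria, shifted down by little: 1 of 28 rose and 22 fell, and 1 and 22 adjusted over the list alone (median log2 -0.26, camera adjusted p = 0.00222). SDHA was 1.75-fold, NDUFA9 1.59-fold, NDUFS3 1.44-fold and UQCRC1 1.56-fold lower. Limma called 8334 of 12445 genes at an adjusted p under 0.05, 4216 higher and 4118 lower. Of these, 853 higher and 799 lower changed at least 2-fold and 3300 changed at least 1.5-fold. With the chip as a block 8371 genes were called, on chip 1 alone 6919 and on chip 2 alone 7316. Medians of the 5 lists that passed had the same sign on both chips and differed by at most 0.34 in log2. Of the genes named by the fixed rule in this comparison, the highest limma adjusted p was 2.11e-11. The other 25 lists did not pass, with camera adjusted p from 0.0666 to 0.999.

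With the scaffold NHERF1 targeted, the question was again which transcripts differ from control. Higher genes included SLC2A3 150.2-fold (log2 7.23, SE 0.07, above the floor on 5 of 6 control arrays), TCEAL9 114-fold (log2 6.83, SE 0.06), BEX3 96.1-fold (log2 6.59, SE 0.11) and RCN1 93.6-fold (log2 6.55, SE 0.09, above the floor on 3 of 6 control arrays). PLAC9 was 71.0-fold (log2 6.15, SE 0.06, above the floor on 4 of 6 control arrays) and IGF2BP3 at least 47.8-fold higher. LAMC1, a laminin chain of basement membrane, was 58.5-fold (log2 5.87, SE 0.06) higher and FSCN1, which bundles actin, 58.0-fold (log2 5.86, SE 0.05) higher. Lower genes included IRX3 109-fold (log2 -6.76, SE 0.09, above the floor on 4 of 6 NHERF1 knockdown arrays), SCGB2A2 at least 73.8-fold and BCAS1 at least 65.8-fold. MLPH was 83.9-fold (log2 -6.39, SE 0.08, above the floor on 2 of 6 NHERF1 knockdown arrays), ORM1 at least 55.5-fold and CPS1 63.7-fold (log2 -5.99, SE 0.08) lower. GPX2 was at least 57.2-fold (above the floor on 1 of 6 NHERF1 knockdown arrays) and PITX1 at least 55.9-fold (above the floor on 2 of 6 NHERF1 knockdown arrays) lower. The luminal epithelial markers went down as a group: 5 of 25 rose and 20 fell, and 5 and 20 adjusted over the list alone (median log2 -1.13, camera adjusted p = 7.23e-07). SPDEF was at least 45.6-fold, AZGP1 at least 10.8-fold and AGR2 48.4-fold lower. Another AGR2 probe changed by -2.56 in log2, against -5.60 for the one used. Against them, among basal and mesenchymal markers 8 of 13 rose and 3 fell, and 8 and 3 adjusted over the list alone (median log2 0.98, camera adjusted p = 0.0125). ACTA2 was 8.09-fold, TAGLN 6.32-fold, SPARC at least 8.71-fold and CDH2 at least 4.15-fold higher. Of the fibroblast markers 5 of 7 rose and 0 fell, and 5 and 0 adjusted over the list alone (median log2 0.93, camera adjusted p = 0.0194). Only 7 of its 16 members were tested, and with no filter on dim probes the list did not pass (camera adjusted p = 0.0651). BGN was 9.09-fold, PDGFRB at least 2.90-fold, COL5A1 1.90-fold and COL3A1 at least 1.87-fold higher. In the mitosis list, 34 of 38 rose and 0 fell, and 34 and 0 adjusted over the list alone (median log2 0.48, camera adjusted p = 1.29e-06). AURKB was 2.31-fold, HMMR 1.93-fold, CDC20 1.75-fold and KIF2C 1.93-fold higher. Genes of S phase and DNA replication went the same way, where 23 of 33 rose and 5 fell, and 23 and 6 adjusted over the list alone (median log2 0.31, camera adjusted p = 0.0103, adjusted p = 0.107 with an estimated correlation). PRIM1 was 2.13-fold, MCM2 2.74-fold, TYMS 1.62-fold and RFC4 1.81-fold higher. Interferon-stimulated genes gave a like count, as 21 of 36 rose and 8 fell, and 21 and 8 adjusted over the list alone (median log2 0.33, camera adjusted p = 0.00800). IFITM3 was 13.7-fold, IFITM2 7.10-fold, IFITM1 29.4-fold (above the floor on 5 of 6 control arrays) and HERC5 at least 13.9-fold (above the floor on 1 of 6 control arrays) higher. NRF2 targets, which detoxify oxidants, moved down, as 4 of 19 rose and 12 fell, and 4 and 12 adjusted over the list alone (median log2 -0.63, camera adjusted p = 0.00275). NQO1 was 12.1-fold, ABCC3 8.82-fold and ME1 4.18-fold lower. By its tested probe AKR1C2 was at least 8.75-fold lower, while 1 of its 5 other probes lay above the floor on 1 of 6 knockdown arrays. The neighbours of ERBB2 in the 17q12 amplicon also moved down: 2 of 15 rose and 9 fell, and 2 and 9 adjusted over the list alone (median log2 -0.31, camera adjusted p = 0.0327). PPP1R1B was 5.31-fold, GRB7 2.02-fold, ORMDL3 2.58-fold and TCAP at least 2.21-fold lower. Another PPP1R1B probe changed by -0.44 in log2, against -2.41 for the one used. On chip 1 alone that list did not pass (camera adjusted p = 0.0563). Among the unfolded protein response genes 4 of 27 rose and 14 fell, and 4 and 14 adjusted over the list alone (median log2 -0.15, camera adjusted p = 0.0428, adjusted p = 0.107 with an estimated correlation). XBP1 was 6.48-fold, WFS1 5.18-fold, ATF3 1.99-fold and SYVN1 1.71-fold lower. The list did not pass on chip 1 alone (camera adjusted p = 0.0563) or without control replicate 5 (camera adjusted p = 0.0531). Oxidative phosphorylation genes shifted down, as 0 of 28 rose and 20 fell, and 0 and 20 adjusted over the list alone (median log2 -0.25, camera adjusted p = 0.00800). NDUFB5 was 1.37-fold, COX6A1 1.39-fold, NDUFS1 1.68-fold and NDUFB8 1.27-fold lower. Limma called 8297 of 12445 genes at an adjusted p under 0.05, 4447 higher and 3850 lower. Of these, 755 higher and 843 lower changed at least 2-fold and 3288 changed at least 1.5-fold. With the chip as a block 8330 genes were called, on chip 1 alone 6940 and on chip 2 alone 7295. Medians of the 10 lists that passed had the same sign on both chips and differed by at most 0.17 in log2. Of the genes named by the fixed rule in this comparison, the highest limma adjusted p was 2.33e-07. The other 20 lists did not pass, with camera adjusted p from 0.0763 to 0.913.

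Knockdown of HER2 itself was compared with control, to show which transcripts differ when the receptor is targeted. Among the higher genes were SLC2A3 158-fold (log2 7.31, SE 0.07, above the floor on 5 of 6 control arrays), PLAC9 108-fold (log2 6.76, SE 0.06, above the floor on 4 of 6 control arrays), TCEAL9 108-fold (log2 6.75, SE 0.06) and MGARP at least 55.2-fold. LAMC1 was 67.6-fold (log2 6.08, SE 0.06), PLAC8 57.9-fold (log2 5.85, SE 0.05), GAL 53.2-fold (log2 5.73, SE 0.10, above the floor on 4 of 6 control arrays) and FSCN1 51.1-fold (log2 5.68, SE 0.05) higher. MGARP is a mitochondrial protein and GAL the neuropeptide galanin. Among the lower genes were IRX3 108-fold (log2 -6.75, SE 0.09, above the floor on 5 of 6 HER2 knockdown arrays), SCGB2A2 at least 73.8-fold, BCAS1 at least 65.8-fold and MLPH 79.2-fold (log2 -6.31, SE 0.08, above the floor on 5 of 6 HER2 knockdown arrays). GPX2 was at least 57.6-fold, IGFBP5 67.5-fold (log2 -6.08, SE 0.06), ORM1 at least 55.5-fold and PITX1 at least 56.7-fold lower. PITX1 and IRX3 are homeobox transcription factors, and GPX2 is a glutathione peroxidase. Luminal epithelial markers fell as a list: 5 of 25 rose and 18 fell, and 5 and 18 adjusted over the list alone (median log2 -1.42, camera adjusted p = 1.98e-05). SPDEF was at least 45.6-fold, AZGP1 at least 10.8-fold and FOXA1 38.8-fold lower. The mitosis list went up, where 28 of 38 rose and 2 fell, and 29 and 2 adjusted over the list alone (median log2 0.42, camera adjusted p = 6.53e-05). HMMR was 2.29-fold, CDC20 1.93-fold, CDK1 1.97-fold and TPX2 1.83-fold higher. NRF2 targets went down, where 3 of 19 rose and 15 fell, and 3 and 15 adjusted over the list alone (median log2 -0.82, camera adjusted p = 7.04e-05). NQO1 was 12.7-fold, ABCC3 19.5-fold (above the floor on 5 of 6 HER2 knockdown arrays), AKR1C2 at least 8.75-fold and AKR1B10 4.15-fold lower. For cholesterol synthesis, 11 of 19 rose and 3 fell, and 11 and 3 adjusted over the list alone (median log2 0.53, camera adjusted p = 0.0389, adjusted p = 0.0585 with an estimated correlation). HMGCS1 was 2.87-fold, PMVK 1.98-fold, INSIG1 2.08-fold and LSS 1.94-fold higher. HMGCS1 encodes an early enzyme of the pathway, and the list did not pass on chip 2 alone (camera adjusted p = 0.112). Oxidative phosphorylation genes shifted down, as 2 of 28 rose and 19 fell, and 2 and 19 adjusted over the list alone (median log2 -0.23, camera adjusted p = 0.0389, adjusted p = 0.0603 with an estimated correlation). NDUFS3 was 1.37-fold, NDUFB5 1.38-fold, COX6A1 1.34-fold and COX5A 1.35-fold lower. That list did not pass on chip 1 alone (camera adjusted p = 0.0728). Limma called 8366 of 12445 genes at an adjusted p under 0.05, 4404 higher and 3962 lower. Of these, 774 higher and 847 lower changed at least 2-fold and 3360 changed at least 1.5-fold. With the chip as a block 8391 genes were called, on chip 1 alone 6971 and on chip 2 alone 7397. Medians of the 5 lists that passed had the same sign on both chips and differed by at most 0.09 in log2. Of the genes named by the fixed rule in this comparison, the highest limma adjusted p was 1.03e-08. The other 25 lists did not pass, with camera adjusted p from 0.127 to 0.960.

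The 3 knockdowns changed many of the same genes, and whether they act alike was asked by setting their log2 changes side by side. Genes with large rises in all 3 included SLC2A3, TCEAL9, PLAC9, LAMC1, BEX3 and IGF2BP3, and those with large falls IRX3, SCGB2A2, BCAS1, MLPH, ORM1 and PITX1. At 2-fold or more, 421 genes were higher in all 3 knockdowns and 535 lower, where independent lists would share 3.22 and 3.68. Unchanged groups simulated against the shared controls had 0 calls in common per pair, as the mean of 20 simulations. The simulated value leaves out real effects and the independent value leaves out the shared controls. Over 12445 genes, which are not independent replicates, the log2 changes of the PMCA2 and HER2 knockdowns correlated with r = 0.842, those of NHERF1 and HER2 with r = 0.883 and those of PMCA2 and NHERF1 with r = 0.851. Spearman's rho was 0.755, 0.794 and 0.737. Since the same control arrays enter each, unchanged groups simulated against them gave r = 0.501. The covariances were 0.656, 0.680 and 0.666, against 0.00311 in the simulation. With controls split by chip, r was 0.829 and 0.834 for PMCA2 and HER2 and 0.872 and 0.874 for NHERF1 and HER2. For PMCA2 and NHERF1 it was 0.838 and 0.843. The split takes out only the noise of shared control arrays, and the simulation holds only the spread between arrays. Control arrays on both chips may be repeats of the same culture. A difference of that culture would then stay in these correlations and in the split counts below. The PMCA2 and HER2 knockdowns shared 3079 higher and 2998 lower genes, against 1492 and 1311 for independent lists, while 632 were called in opposite directions. For NHERF1 and HER2 the shared counts were 3266 and 2976 against 1574 and 1226, with 485 opposite. For PMCA2 and NHERF1 they were 3053 and 2891 against 1506 and 1274, with 702 opposite. With one knockdown read on chip 1 and the other on chip 2, or the reverse, each against that chip's controls (3 arrays per group), the shared higher and lower counts were 2445 and 2453 or 2476 and 2469 for PMCA2 and HER2, 2668 and 2393 or 2595 and 2464 for NHERF1 and HER2, and 2407 and 2353 or 2497 and 2323 for PMCA2 and NHERF1. Lists that passed in none of the 6 comparisons, with their lowest camera adjusted p, were ERBB receptors and ligands (0.172), ERK pathway output (0.185), FOXO targets and PI3K feedback (0.286), calcium pumps, channels and sensors (0.324), ERM and PDZ scaffold partners (0.110), milk and secretory genes (0.169), p53 targets (0.169), hypoxia and glycolysis (0.110), heat shock proteins (0.420), receptor endocytosis and trafficking (0.443), leukocyte and endothelial markers (0.217) and estrogen-response genes of ER-positive breast lines (0.110). In the 40 calls that passed, median, mean and test had the same sign, and in 39 of those that did not pass they differed. With an estimated correlation 29 of the 40 calls held. That correlation comes from the spread between arrays of a group, which may be technical, so it may leave out variation between cultures.

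**Figure D2:**
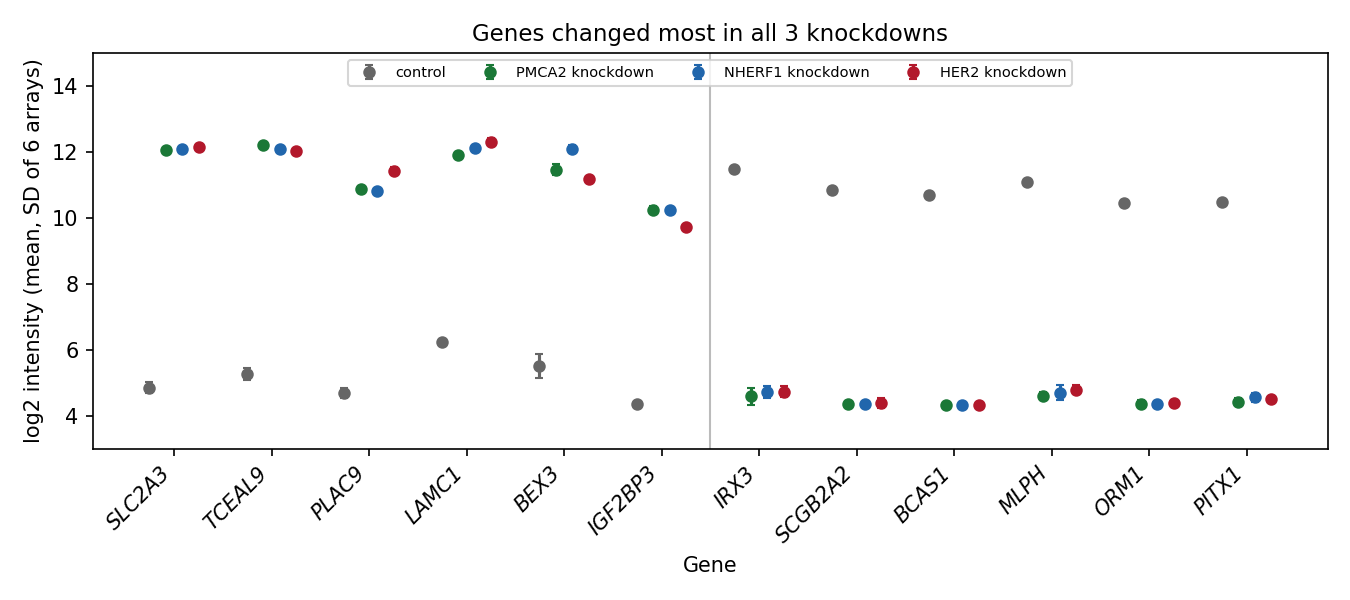
Mean log2 intensity (vertical axis, bars are the SD of 6 arrays) in the 4 groups for the 6 genes with the largest fitted rise and the 6 with the largest fitted fall in all 3 knockdowns. The 3 knockdowns lie on one side of control for every gene plotted.

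**Figure D3:**
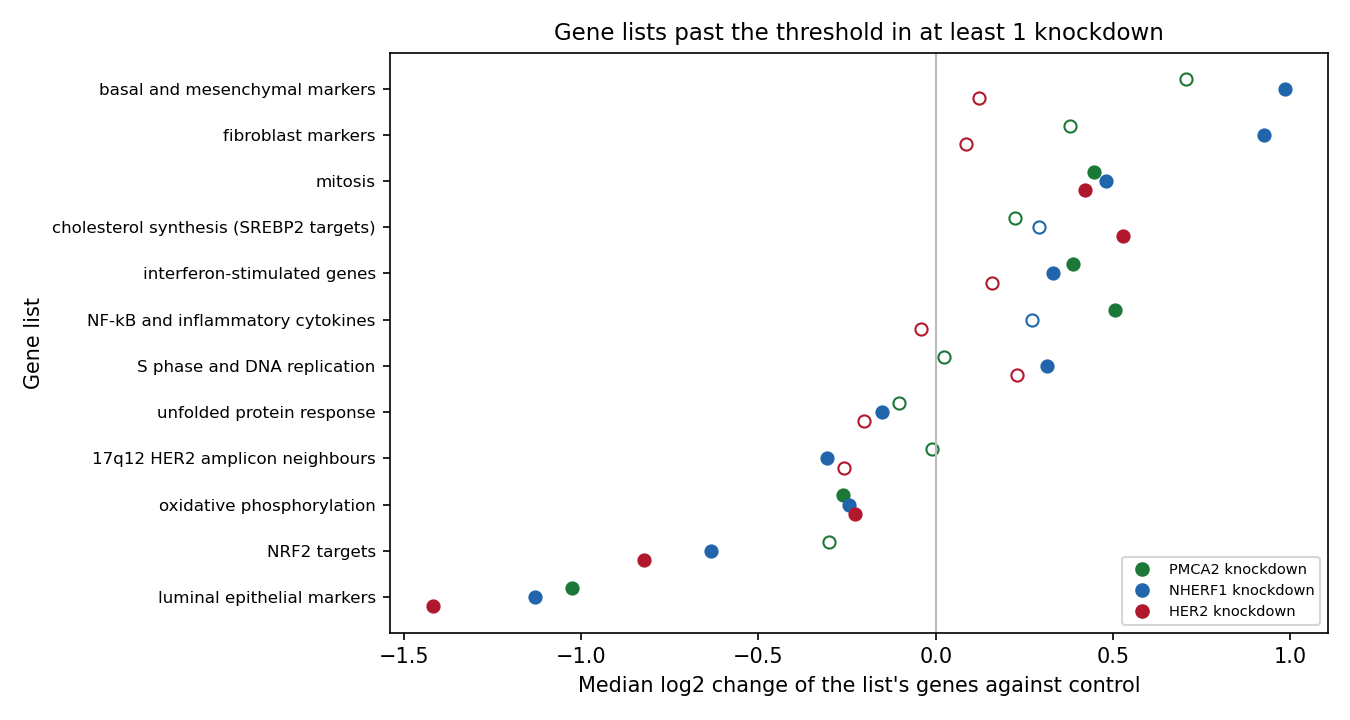
Median log2 change against control (horizontal axis) of the genes of each list that passed camera in at least 1 knockdown, with filled points where the list passed and open points where it did not. Luminal markers lie lowest in all 3 knockdowns, and mitosis genes lie above 0 in all 3.

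The PMCA2 and HER2 knockdowns were set directly against each other to test whether they differ, with folds given for PMCA2 over HER2. PSG4, a pregnancy-specific glycoprotein, was 23.3-fold (log2 4.54, SE 0.09, above the floor on 3 of 6 HER2 knockdown arrays) higher. CGA, the shared subunit of glycoprotein hormones, was 17.2-fold (log2 4.11, SE 0.11), SIGLEC6 17.2-fold (log2 4.11, SE 0.06) and UGT1A7 18.4-fold (log2 4.20, SE 0.08) higher. Against control, PSG4 changed by 1.63 in log2 with PMCA2 and -2.91 with HER2 knocked down (-1.09 to -0.97 for its other probes). PSG and UGT1A genes have close relatives, so their probes may read more than 1 gene. GTSF1 was at least 50.8-fold, RBP7 at least 32.0-fold (above the floor on 2 of 6 PMCA2 knockdown arrays), NCCRP1 12.1-fold (log2 -3.59, SE 0.08, above the floor on 4 of 6 PMCA2 knockdown arrays) and MT1G at least 8.92-fold lower. In the NF-kB and inflammatory cytokines list 15 of 23 were higher and 0 lower, and 15 and 0 adjusted over the list alone (median log2 0.33, camera adjusted p = 1.73e-05). SAA1 was 11.7-fold (above the floor on 4 of 6 HER2 knockdown arrays), CCL5 3.27-fold, LCN2 at least 3.13-fold (above the floor on 1 of 6 HER2 knockdown arrays) and SOD2 1.99-fold higher. Of the lysosome and autophagy genes 18 of 24 were higher and 0 lower, and 18 and 0 adjusted over the list alone (median log2 0.37, camera adjusted p = 2.64e-05). GABARAPL1 was 3.62-fold, GLA 1.97-fold, WIPI1 2.55-fold and ULK1 2.34-fold higher. Among NRF2 targets 14 of 19 were higher and 1 lower, and 14 and 1 adjusted over the list alone (median log2 0.28, camera adjusted p = 3.32e-04). AKR1B10 was 4.25-fold, HMOX1 3.79-fold, SRXN1 2.28-fold and ABCC3 2.33-fold (above the floor on 5 of 6 HER2 knockdown arrays) higher. Among calcium-responsive genes 13 of 26 were higher and 6 lower, and 13 and 6 adjusted over the list alone (median log2 0.15, camera adjusted p = 0.0219). S100P was 6.11-fold, CAMK2D at least 3.68-fold, S100A8 2.95-fold and S100A9 1.92-fold higher. Of the apoptosis regulators 12 of 28 were higher and 3 lower, and 12 and 3 adjusted over the list alone (median log2 0.14, camera adjusted p = 0.0219). BCL2L1 was 1.55-fold, PMAIP1 2.58-fold, CFLAR 2.10-fold and BNIP3L 1.58-fold higher. In the unfolded protein response list 14 of 27 were higher and 2 lower, and 14 and 2 adjusted over the list alone (median log2 0.16, camera adjusted p = 0.0219, adjusted p = 0.0925 with an estimated correlation). DNAJC3 was 1.84-fold, EDEM1 1.73-fold, SELENOS 1.32-fold and SYVN1 1.48-fold higher. The lists that were lower included the amino acid response, where 4 of 26 were higher and 18 lower, and 4 and 18 adjusted over the list alone (median log2 -0.31, camera adjusted p = 9.17e-04). PHGDH was 4.53-fold, CTH 3.97-fold, PSAT1 1.98-fold and PCK2 2.11-fold lower. For S phase and DNA replication 2 of 33 were higher and 22 lower, and 3 and 24 adjusted over the list alone (median log2 -0.28, camera adjusted p = 8.43e-04, adjusted p = 0.0548 with an estimated correlation). PRIM1 was 1.89-fold, UNG 2.14-fold, MCM7 1.33-fold and UHRF1 1.34-fold lower. In cholesterol synthesis 2 of 19 were higher and 13 lower, and 2 and 13 adjusted over the list alone (median log2 -0.30, camera adjusted p = 0.0218). PMVK was 1.69-fold, HMGCS1 1.69-fold, IDI1 1.41-fold and ACAT2 1.32-fold lower. In fatty acid synthesis 2 of 18 were higher and 10 lower, and 2 and 10 adjusted over the list alone (median log2 -0.26, camera adjusted p = 0.0219, adjusted p = 0.126 with an estimated correlation). MID1IP1 was 3.17-fold, ACACB 2.57-fold, FADS1 1.80-fold and SCD 1.37-fold lower. Metallothioneins, which bind zinc and other metals and resemble one another closely, gave the last call, as 1 of 8 were higher and 5 lower, and 2 and 5 adjusted over the list alone (median log2 -0.70, camera adjusted p = 0.0420, adjusted p = 0.0698 with an estimated correlation). MT1H was at least 2.72-fold, MT1X 1.57-fold and MT1F 1.84-fold (above the floor on 5 of 6 PMCA2 knockdown arrays) lower. The list did not pass on chip 2 alone (camera adjusted p = 0.0675), without PMCA2 knockdown replicate 1 (camera adjusted p = 0.0503) or without HER2 knockdown replicate 3 (camera adjusted p = 0.0585). Limma called 6889 of 12445 genes at an adjusted p under 0.05, 3293 higher and 3596 lower. Of these, 360 higher and 216 lower changed at least 2-fold and 1620 changed at least 1.5-fold. With the chip as a block 6931 genes were called, on chip 1 alone 5103 and on chip 2 alone 5537. Medians of the 11 lists that passed had the same sign on both chips and differed by at most 0.14 in log2. Of the genes named by the fixed rule in this comparison, the highest limma adjusted p was 1.94e-07. The other 19 lists did not pass, with camera adjusted p from 0.217 to 0.999.

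Between the NHERF1 and HER2 knockdowns, E2F5 13.0-fold (log2 3.70, SE 0.08, above the floor on 4 of 6 HER2 knockdown arrays), GABBR2 10.8-fold (log2 3.43, SE 0.05), HCLS1 at least 7.78-fold and PLOD2 9.14-fold (log2 3.19, SE 0.11, above the floor on 5 of 6 HER2 knockdown arrays) were higher with NHERF1 knocked down. E2F5 belongs to the E2F transcription factors and PLOD2 modifies collagen lysines. MT1G at least 8.60-fold (above the floor on 2 of 6 NHERF1 knockdown arrays), BMP5 8.66-fold (log2 -3.11, SE 0.06) and RBP7 7.15-fold (log2 -2.84, SE 0.09) were lower, as was NHERF1 itself, 7.77-fold (log2 -2.96, SE 0.05). Of the NF-kB and inflammatory cytokines, 11 of 23 were higher and 3 lower, and 11 and 3 adjusted over the list alone (median log2 0.18, camera adjusted p = 0.0259). SAA1 was 4.36-fold (above the floor on 4 of 6 HER2 knockdown arrays), SOD2 1.66-fold, CCL5 1.77-fold and IL1B at least 1.58-fold higher. The list did not pass on chip 2 alone (camera adjusted p = 0.0512). Metallothioneins were lower, as 0 of 8 were higher and 5 lower, and 0 and 5 adjusted over the list alone (median log2 -0.93, camera adjusted p = 0.00849). MT1G was at least 8.60-fold (above the floor on 2 of 6 NHERF1 knockdown arrays), MT1H at least 2.72-fold, MT2A 2.04-fold and MT1F at least 2.00-fold (above the floor on 3 of 6 NHERF1 knockdown arrays) lower. Limma called 6503 of 12445 genes at an adjusted p under 0.05, 3337 higher and 3166 lower. Of these, 250 higher and 184 lower changed at least 2-fold and 1297 changed at least 1.5-fold. With the chip as a block 6519 genes were called, on chip 1 alone 4627 and on chip 2 alone 5093. Medians of the 2 lists that passed had the same sign on both chips and differed by at most 0.11 in log2. Of the genes named by the fixed rule in this comparison, the highest limma adjusted p was 1.52e-10. The other 28 lists did not pass, with camera adjusted p from 0.105 to 0.969.

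In the last comparison, PSG4 was 16.8-fold (log2 4.07, SE 0.09) higher with PMCA2 than with NHERF1 knocked down, and so were GAS6 16.5-fold (log2 4.04, SE 0.08, above the floor on 4 of 6 NHERF1 knockdown arrays), SPRR3 13.9-fold (log2 3.80, SE 0.06) and KRT23 13.5-fold (log2 3.76, SE 0.09). PSG4 changed against control by 1.63 in log2 with PMCA2 and -2.44 with NHERF1 knocked down (-1.03 to -0.92 for its other probes). GTSF1 was at least 29.7-fold, COX7B2 at least 24.4-fold, MAGEC2 27.5-fold (log2 -4.78, SE 0.06) and TCEAL8 at least 15.6-fold lower. Lysosome and autophagy genes were higher as a list, as 19 of 24 were higher and 0 lower, and 19 and 0 adjusted over the list alone (median log2 0.50, camera adjusted p = 7.06e-07). SQSTM1 was 1.82-fold, WIPI1 2.62-fold, CTSB 2.07-fold and CTSD 2.05-fold higher. Neighbours of ERBB2 in the 17q12 amplicon were higher, as 10 of 15 were higher and 1 lower, and 10 and 1 adjusted over the list alone (median log2 0.26, camera adjusted p = 0.00742). GRB7 was 1.83-fold, PPP1R1B 1.85-fold, PGAP3 1.75-fold and GSDMB 1.34-fold higher. In the calcium-responsive genes 16 of 26 were higher and 5 lower, and 16 and 5 adjusted over the list alone (median log2 0.20, camera adjusted p = 0.00742). ANXA1 was 2.79-fold, S100P 2.45-fold, S100A7 4.46-fold and PPP3CC 1.83-fold higher. Among NF-kB and inflammatory cytokines 15 of 23 were higher and 3 lower, and 15 and 3 adjusted over the list alone (median log2 0.26, camera adjusted p = 0.0144). LCN2 was at least 3.18-fold, SAA1 2.70-fold, CCL5 1.84-fold and NFKB2 1.56-fold higher. In the unfolded protein response 16 of 27 were higher and 4 lower, and 17 and 4 adjusted over the list alone (median log2 0.20, camera adjusted p = 0.00742, adjusted p = 0.0647 with an estimated correlation). ATF3 was 2.57-fold, DNAJC3 2.13-fold, WFS1 2.11-fold and PPP1R15A 1.84-fold higher. Of the NRF2 targets 12 of 19 were higher and 3 lower, and 12 and 3 adjusted over the list alone (median log2 0.33, camera adjusted p = 0.00742, adjusted p = 0.0647 with an estimated correlation). HMOX1 was 2.28-fold, ABCC2 2.24-fold (above the floor on 5 of 6 NHERF1 knockdown arrays), TALDO1 1.46-fold and TXNRD1 1.49-fold higher. Genes of S phase and DNA replication were lower, as 4 of 33 were higher and 25 lower, and 4 and 25 adjusted over the list alone (median log2 -0.38, camera adjusted p = 6.65e-05). PRIM1 was 2.10-fold, UNG 1.96-fold, CHAF1B 1.98-fold and RFC4 1.82-fold lower. Limma called 7133 of 12445 genes at an adjusted p under 0.05, 3396 higher and 3737 lower. Of these, 327 higher and 204 lower changed at least 2-fold and 1695 changed at least 1.5-fold. With the chip as a block 7181 genes were called, on chip 1 alone 5424 and on chip 2 alone 5779. Medians of the 7 lists that passed had the same sign on both chips and differed by at most 0.06 in log2. Of the genes named by the fixed rule in this comparison, the highest limma adjusted p was 2.19e-08. The other 23 lists did not pass, with camera adjusted p from 0.118 to 0.948.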

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

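Values of single arrays were taken as apart where the gap to the nearest other array of the group took up most of the range of its 6 arrays. This held for 44 of 724 sets of 6 values, and chance at 1 in 20 gives 36.2. The tests of the HER2 knockdown array were fixed before their own results were seen, that of probe pairs after the others were known, and the array was picked after its count was seen. Levels are log2 intensities, each against the mean of the other 5 arrays.

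Control replicate 1 had IFITM2 at 10.15 against 10.28. In replicate 2 of that group stood COX6A1 at 11.24 against 11.42 and GRB7 at 10.67 against 10.79. Replicate 4 gave ABCC2 at 6.51 against 6.22 and EDEM1 at 7.39 against 7.68. Replicate 5 gave HERC5 at 4.93 against 4.29, IL6 at 5.08 against 4.48 and NCCRP1 at 9.09 against 9.19. Replicate 6 gave IGF2BP3 at 4.48 against 4.32 and the mean of the calcium pumps, channels and sensors list at 7.03 against 6.97. PMCA2 knockdown replicate 1 had CAPN6 at 10.66 against 10.34 and the mean of the amino acid response (ATF4 targets) list at 8.54 against 8.59. In replicate 2 of that group stood AKR1B10 at 9.58 against 9.35, BEX3 at 11.13 against 11.52, EDEM1 at 8.72 against 8.47 and PGAP3 at 10.91 against 10.70. Replicate 3 gave IL1B at 5.43 against 5.78, LAMC1 at 11.74 against 11.95 and the mean of the receptor endocytosis and trafficking list at 8.17 against 8.24. Replicate 4 gave MT1H at 4.51 against 4.25. Replicate 5 gave PSG4 at 9.16 against 9.33. NHERF1 knockdown replicate 1 had AURKB at 9.39 against 9.59. In replicate 2 of that group stood TPX2 at 9.40 against 9.52 and the mean of the ERM and PDZ scaffold partners list at 7.52 against 7.56. Replicate 3 gave IRX3 at 5.04 against 4.65 and LCN2 at 4.54 against 4.32. Replicate 4 gave MT1H at 4.40 against 4.29 and the mean of the S phase and DNA replication list at 9.31 against 9.26. Replicate 5 gave UGT1A7 at 7.34 against 7.18. Replicate 6 gave PGAP3 at 9.72 against 9.97. HER2 knockdown replicate 1 had MCM2 at 8.68 against 9.03. In replicate 2 of that group stood AKR1C2 at 4.61 against 4.36 and BCL2L1 at 9.91 against 9.76. Replicate 3 gave ACTA2 at 7.86 against 8.06, BEX3 at 11.06 against 11.21, GAL at 11.02 against 10.54, MGARP at 10.60 against 10.40, NHERF1 at 11.17 against 11.30, SDHA at 10.68 against 10.43, TAGLN at 8.22 against 8.53, ULK1 at 8.04 against 8.54, WIPI1 at 7.0 against 6.52 and the mean of the mitosis list at 9.37 against 9.32. Replicate 4 gave HMMR at 9.42 against 9.54.

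HER2 knockdown replicate 3 held 10 of the 44 values, more than any other array. RNA of control cells on that array would move its deviation along the control minus HER2 knockdown difference, but the coefficient over all genes was 0.00191, which argues against it. The SD over genes of its deviation from its group was 0.18 in log2, the highest of 24 arrays, against a median of 0.15, but this restates that its values lay apart. A difference in its RNA would be read alike by different probes of a gene, and deviations of probe pairs over 3390 genes correlated with r = 0.109, against a median of 0.0756 and with 3 arrays higher. A noisier hybridisation and a difference in RNA thus cannot be told apart, array position and culture stay open, and no biological explanation was tested, since the labels give none for a single array.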

How the results depend on the processing

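The thresholds of at least 2-fold and normexp on all probes (offset 50) were chosen after seeing the data, and the other alternatives before. All 9963 of 9963 values of named genes kept direction and side of the threshold of adjusted p, over 17 alternatives and 24 left-out arrays. The fold thresholds are not among these, and of 243 named values 20 lie under 1.5-fold and 75 under 2-fold. Apart from the targets, these genes were picked from the same data for large changes or small p. Keeping them was thus likely from the start and says little of other genes. With all probes, the same probe was read again for each named gene. The deposited values were already normalized, so other scalings could change little and do not test the authors' own normalization. Outside the fold thresholds, genes changed numbered 6919 to 10904, 6940 to 10869 and 6971 to 11044 against control for PMCA2, NHERF1 and HER2, and 5103 to 8927, 4627 to 8333 and 5424 to 9249 for PMCA2 with HER2, NHERF1 with HER2 and PMCA2 with NHERF1. A fold of at least 1.5 leaves 3300, 3288, 3360, 1620, 1297, 1695 in that order and a fold of at least 2 leaves 1652, 1598, 1621, 576, 434, 531, fewer because small changes are left out. Leaving out each array gave genes changed of 8188 to 8394, 8122 to 8369, 8182 to 8371, 6689 to 6918, 6244 to 6502 and 6872 to 7216.

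The log2 change of NHERF1 in its knockdown was -3.68 to -3.33 (-3.64 to -3.60 with an array left out), that of ERBB2 in the HER2 knockdown -0.93 to -0.74 (-0.92 to -0.90), and that of ATP2B2, untested, -0.05 to -0.01 (-0.06 to 0.01). Correlations moved by more than their spread in 5 cases: 0.844 for PMCA2 and NHERF1 with no background correction, 0.837 for PMCA2 and HER2 with chip 1 alone, 0.879 for NHERF1 and HER2 with chip 1 alone, 0.845 for PMCA2 and NHERF1 with chip 1 alone, 0.845 for PMCA2 and NHERF1 with all probes. The left-out ranges were 0.841 to 0.842, 0.883 to 0.883 and 0.849 to 0.851.

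The number of the 6 comparisons in which a list passed was held as kept within 1.5 times. Within that limit it still ranged over the alternatives from 2 to 3 for 17q12 HER2 amplicon neighbours (2 as reported), 4 to 5 for NF-kB and inflammatory cytokines (4 as reported), 3 to 6 for NRF2 targets (4 as reported), 3 to 4 for S phase and DNA replication (3 as reported), 2 to 3 for cholesterol synthesis (2 as reported), 2 to 3 for interferon-stimulated genes (2 as reported), 2 to 3 for lysosome and autophagy (2 as reported), 2 to 3 for oxidative phosphorylation (3 as reported), 2 to 4 for unfolded protein response (3 as reported). It moved by more in the following cases, and the cause was not tested. With no background correction it was metallothioneins and zinc response 1. With no filter on dim probes it was amino acid response 2, fibroblast markers 0. With strict filter on dim probes it was 17q12 HER2 amplicon neighbours 1, cholesterol synthesis 1, metallothioneins and zinc response 1. With replicate block it was cholesterol synthesis 1 (HER2 with control was lost), metallothioneins and zinc response 1 (PMCA2 with HER2 was lost). With chip 1 alone it was 17q12 HER2 amplicon neighbours 1, fibroblast markers 2. With chip 2 alone it was NF-kB and inflammatory cytokines 2, cholesterol synthesis 1, metallothioneins and zinc response 1. With same chip positions averaged across chips it was cholesterol synthesis 1. With all probes it was ERM and PDZ scaffold partners 1, amino acid response 2, estrogen-response genes 3, fibroblast markers 2, hypoxia and glycolysis 2, leukocyte and endothelial markers 1, metallothioneins and zinc response 1, p53 targets 1. With only the 2 groups compared it was cholesterol synthesis 1. With camera with estimated correlation it was S phase and DNA replication 1, cholesterol synthesis 1, fatty acid synthesis 0, interferon-stimulated genes 1, metallothioneins and zinc response 1, unfolded protein response 0. With fry in place of camera it was 4 for ERK pathway output, FOXO targets and PI3K feedback, 5 for ERBB receptors and ligands, ERM and PDZ scaffold partners, fatty acid synthesis, heat shock proteins, leukocyte and endothelial markers, luminal epithelial markers, mitosis, receptor endocytosis and trafficking, 6 for 17q12 HER2 amplicon neighbours, S phase and DNA replication, amino acid response, apoptosis regulators, basal and mesenchymal markers, calcium pumps, channels and sensors, calcium-responsive genes, cholesterol synthesis, estrogen-response genes, fibroblast markers, hypoxia and glycolysis, interferon-stimulated genes, lysosome and autophagy, metallothioneins and zinc response, milk and secretory genes, oxidative phosphorylation, p53 targets, unfolded protein response, as fry asks another question. Directions under fry were reversed for apoptosis regulators, PMCA2 vs control (adjusted p = 0.00851), hypoxia and glycolysis, PMCA2 vs control (adjusted p = 2.23e-07), amino acid response (ATF4 targets), NHERF1 vs control (adjusted p = 7.41e-04), hypoxia and glycolysis, HER2 vs control (adjusted p = 0.00448), basal and mesenchymal markers, PMCA2 vs HER2 (adjusted p = 2.38e-08), hypoxia and glycolysis, PMCA2 vs HER2 (adjusted p = 2.67e-04), ERM and PDZ scaffold partners, NHERF1 vs HER2 (adjusted p = 2.02e-09), ERK pathway output, PMCA2 vs NHERF1 (adjusted p = 0.00277), interferon-stimulated genes, PMCA2 vs NHERF1 (adjusted p = 2.17e-06), heat shock proteins, PMCA2 vs NHERF1 (adjusted p = 4.36e-12), leukocyte and endothelial markers, PMCA2 vs NHERF1 (adjusted p = 0.0464). A list's sign counted as reversed only where it passed in either setting, a definition made after seeing the output. In 133 of 7734 list values the sign differed and neither passed. Without 1 array, the metallothioneins passed in 1 to 2 comparisons (1 without PMCA2 knockdown replicate 1 and without HER2 knockdown replicate 3) and the unfolded protein response in 2 to 3 (2 without control replicate 5).

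Replicate numbers were checked as a pairing: 4 of 36 same-numbered pairs had deviations correlated over 0.1. The mean r per pair of groups was 0.000832 to 0.0433, above 0 in each, so a weak shared factor is not excluded. With the replicate block, genes changed numbered 8391, 8329, 8391, 6946, 6535, 7173 in the order above. The series' own processed values are the main input, so the alternative that would use them was not run. Signal over background limits dim genes, such as ATP2B2.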

Other observations

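Chosen after the result was seen were the list of placental genes, the counts of genes on one side of the floor, the 17q12 tests and both ERBB2 tests, and the others were planned. Placental trophoblast genes were counted from a list written after levels of some had been seen, so the counts are no independent evidence. Of 48 such genes, 33 were tested, and with PMCA2 knocked down 25 rose and 5 fell against control, with NHERF1 16 and 10, and with HER2 15 and 11. Against the HER2 knockdown, 23 were higher with PMCA2 knocked down and 1 lower, and 17 were higher with NHERF1 knocked down and 2 lower. Between PMCA2 and NHERF1, 18 were higher with PMCA2 knocked down and 6 lower. Higher with PMCA2 than with HER2 knocked down were ERVW-1 (log2 2.82, SE 0.07), the gene of syncytin, CYP19A1 (log2 3.30, SE 0.09), the gene of aromatase, CYP11A1 (log2 2.50, SE 0.08) and GCM1 (log2 1.86, SE 0.09). Other CYP19A1 probes differed by 0.15 to 2.49. With NHERF1 over HER2 knocked down, CYP11A1 (log2 2.03, SE 0.08), SIGLEC6 (log2 1.61, SE 0.06) and ERVW-1 (log2 1.08, SE 0.07) were higher. All 7 PSG genes tested were also higher with PMCA2 than with HER2 knocked down, although their probes may read close relatives. This held in each of 4 scalings (quantile, no background correction, median and cyclic loess). The deposited values were already normalized, so these scalings could change little and do not test the authors' normalization. Further probes of 5 of the PSG genes differed by 0.69 to 2.89 in log2 between those 2 knockdowns. Against control 7 rose with PMCA2 knocked down, while 6 fell with NHERF1 (5 with no background correction) and 6 with HER2. PSG4 changed in log2 by -2.44 with NHERF1 (-1.03 to -0.92 for its other probes) and by -2.91 with HER2 (-1.09 to -0.97 for its other probes), where 3 of 6 arrays lay above the floor. The other 6 lay at 4.27 to 4.91 in control, near the lowest signal of measured probes (4.65). PAGE4 was highest in the NHERF1 knockdown, by 2.08 (SE 0.07) in log2 over the HER2 knockdown. Control SKBR3 cells already carried some of these transcripts, with XAGE2 at 10.34 and VGLL1 at 10.71.

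In all, 135 genes had their tested probe below the floor on all 6 control arrays and above it on all 18 knockdown arrays, among them HSD3B1, CAPN6 and IGF2BP3. The opposite held for 115 genes, among them SCGB2A2, SPDEF, AZGP1 and BCAS1.

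The 3 knockdowns shared a large change against control, which may come from the control arrays, a chip gradient, cells of another line or the treatment. A smooth gradient along chip positions is argued against by its largest coefficient of 0.00528. That coefficient compares positions within a group, so a step between the positions of control and of the knockdowns would not be seen. Loss of the 17q12 amplification, as in a line without it, would lower that list by 1 or more in log2. Its median was -0.0107 (SD 0.64 over 15 genes) with PMCA2 and -0.26 (SD 0.70 over 15 genes) with HER2 knocked down. Both lie above that limit by more than the SD, narrowly with HER2. This argues against that loss with PMCA2, and only weakly with HER2. With NHERF1 the median was -0.31 (SD 0.78 over 15 genes), within the SD of that limit, so by this rule the loss stays open. The SD is the spread over genes and not the precision of the median. The rule thus does not set the NHERF1 and HER2 knockdowns apart, whose medians are close. A comparison with the luminal list (smallest difference 0.823) decided nothing. Another line that keeps the amplification would not be seen by this test, so cells of another line as such are not argued against. A control culture that alone differed cannot be told apart from a response to knockdown, as both give SDs of change of like size (smallest over largest 0.985), and such a response stays untested.

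ERBB2 was lower with NHERF1 knocked down than with HER2 knocked down. Swapped labels are argued against by NHERF1, at -2.96 in log2 between the same groups. Behaviour of a single probe stays open, because the dimmer ERBB2 probe differed by -0.30 with 3 of 6 NHERF1 arrays below all HER2 arrays. An effect of NHERF1 on ERBB2 is a biological candidate explanation that was not tested further.

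Splits of the 12 arrays of each comparison into groups of 6, 100 drawn of 462, gave as many genes in 1 of 100 for each comparison, the real split itself. Arrays of a group are so alike that mixed splits could hardly give as many. The splits thus show only that the groups differ beyond the spread between arrays. Since the arrays of a group may be technical repeats, this does not exclude a chance difference between cultures. The real counts, fitted on the groups compared, were 8323, 8378, 8268, 6685, 6390, 7100 in the order used above (PMCA2, NHERF1 and HER2 with control, PMCA2 with HER2, NHERF1 with HER2, PMCA2 with NHERF1), and the highest other counts were 1, 1, 0, 3, 929, 2.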
